A study of Homo sapiens with 6 samples.

How the data were processed

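Poly(A) RNA of A431 cells transduced with lentivirus for RBM3 or for EGFP and selected with puromycin was sequenced, with 3 libraries per group, on an Illumina NovaSeq instrument as paired reads from a stranded library kit, per the labels' protocols. The submitters' processing notes name fastp, HISAT2, RSEM and DESeq2 and the build GRCh38.p13, without versions, roles or settings, and whether counting used the strand is not given in the sources used here. Antisense and overlapping genes are therefore uncertain. The protocol for RNA extraction names the cell line C918 where all other labels say A431, and the labels' A431 was used.

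The deposited values are a score per gene, an abundance normalized by the authors for gene length and depth and given to 2 decimals. Whether they are TPM or FPKM is not stated. They are not counts although the table was deposited as such: 0.642% of the values above 0 were whole numbers. Low values were searched for steps of 1 read, and in the best case between 42.9% and 72.7% of them per library were whole multiples within 0.1 of a step, so reads and depth were not recovered. No interval from counting error can be given. The table holds 1174 genes. Of the 336 with a mean of at least 5, 315 (93.8%) had an absolute log2 ratio of the group means of at least 0.9, and 1069 of the 1174 separated the groups fully. The table thus appears to have been selected on the difference between these same libraries, and the criterion is not stated. Tests below run on that selection and are not independent evidence of a difference, and no enrichment against the genome was possible. Gene names came from the deposited table, in which 105 genes had none, and from a gene name table that matched 1170 identifiers. Gene types, coordinates, lengths and GC content came from GENCODE 29 on GRCh38, which held 1156.

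The tests fixed before the data were examined assumed counts. Because the values are normalized, limma on log2(value + 0.1) was used in place of a count test, with the model of group alone, empirical Bayes moderation with an abundance trend and robust settings, and Benjamini-Hochberg adjustment over 1173 genes (1 gene at 0 in all libraries was left out). A call is an adjusted p under 0.05. Fold changes are on the log2(value + 0.1) scale, which understates the change of low genes, and group means are of the values as deposited. The 28 programme lists and 6 quality lists were also fixed beforehand. Lists with at least 3 members in the table (14 of them) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which asks whether a list's genes move one way on balance and not whether they differ from other genes. Camera's background here is the rest of the selected table. Genes were named by a rule fixed beforehand: the 8 largest increases and the 8 largest decreases among called genes with a mean of at least 5, full separation of the groups and an approved symbol, the 2 largest called members with such a mean in each list with at least 3 called members, and all called members of smaller lists. The rule was written for CPM and applied here to the deposited values. Other names were chosen after the values were seen. Of the genes the rule takes, 2 are not reported here.

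Terms of the annotation in the deposited table (241 with at least 10 called genes) were tested for an excess of one direction by Fisher's exact test, 2-sided, against all called genes with a term. Higher and lower genes were compared in transcript length and GC content by the area under the ROC curve with 95% bootstrap intervals from 2000 draws, and shares by chromosome by permutation. Alternatives covered 3 scalings of the table, a filter on low values, blocks by 2 sets of replicate numbers, each library left out, stricter thresholds, other list tests, other pseudocounts and plain moderation. On simulated data made from the 1173 genes' own means and spread, with 200 genes changed, the limma step recovered 14% of genes changed 1.5-fold, 44% of those changed 2-fold, 94% at 4-fold and 98% at 8-fold, with 5 false calls (3.85% of calls). In the table itself 1118 genes were called, and the adjustment depends on that share. These rates therefore do not describe the calls in the selected table. Analyses used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.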

Results

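Gene expression was compared between A431 cells labelled as stably overexpressing RBM3 and A431 cells that carried an EGFP control vector. A431 is an established human line from an epidermoid carcinoma with amplified EGFR, and RBM3 is a cold-inducible RNA-binding protein. There were 3 poly(A) RNA libraries per group, described by the submitters as biological replicates. The table used here lists 1174 genes, 979 of them protein coding, with an abundance normalized for length and depth, rounded to 2 decimals. Summed over the table, these values came to between 16324 and 19525 per library, which is not a sequencing depth. The depth of the libraries is therefore unknown. Of the 1174 genes, 1069 (91.1%) had all 3 values of one group above all 3 of the other, against 10% by chance. The list thus holds mostly genes that differ between the groups, with 105 that overlap. How many genes were measured but not listed is not known here. RBM3 itself is not among the genes of the table used here, so the overexpression was not checked in these values and rests on the labels. In a table that appears to be selected on the difference between the groups, the absence of RBM3 is unexplained. EGFR, KRT5 and TP63 are not among the listed genes either. Across the listed genes, Pearson correlations of log2 values lay between 0.966 and 0.972 within groups and between 0.722 and 0.749 between groups. The gap between these ranges is at least partly set by the apparent listing on the difference, so it does not describe the whole transcriptome.

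The comparison asked which transcripts differ when RBM3 is overexpressed. The listed keratin KRT14, the type I keratin of basal keratinocytes, was 11.8-fold lower with RBM3, at 2006 ± 78.4 (SD, n = 3) in the control and 170 ± 19.3 (SD, n = 3) in the RBM3 libraries. The mucosal keratin KRT4 fell from 862 ± 145 to 134 ± 10.0, and the aldehyde dehydrogenase ALDH3A1 from 169 ± 33.4 to 30.2 ± 3.39. Among the genes that rose were C15orf48, a small mitochondrial protein gene (4.17 ± 1.06 to 78.8 ± 2.02), the DNA repair gene MGMT (1.83 ± 0.41 to 25.3 ± 1.33) and the crosslinking enzyme TGM2 (0.903 ± 0.622 to 17.4 ± 5.86). By limma on log2(value + 0.1), 593 of 1173 tested genes were higher and 525 lower with RBM3 at a Benjamini-Hochberg adjusted p under 0.05. Because the genes appear to have been listed by their difference, these counts describe the list and do not estimate the share of the transcriptome that changed. Scaling the table by the median of ratios shifted the median log2 change of the tested genes from 0.83 to 0.51 and left 544 genes higher and 547 lower. That scaling takes most genes as unchanged, whereas 1118 of the 1173 tested genes were called. Neither median therefore measures a shift of the transcriptome.

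**Figure D1:**
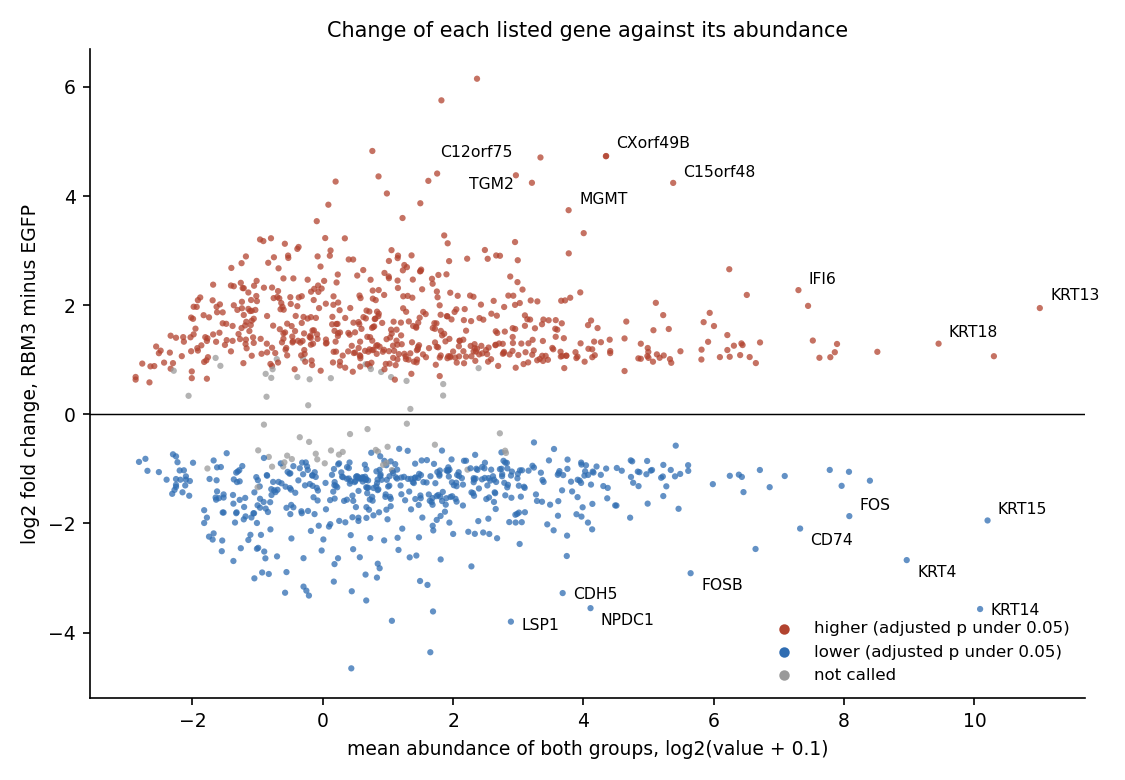
Change of each tested gene (vertical axis, log2 fold change of RBM3 minus EGFP) against its mean abundance over both groups (horizontal axis, log2 of value + 0.1), 1 point per gene, coloured by the limma call. Genes fall into 593 higher and 525 lower, and KRT14 and KRT13 stand out among the most abundant.

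The largest increases by the naming rule began with CXorf49B (gene ENSG00000215113, GRCh38 chromosome X, 71763424 to 71767204), with a log2 fold change of 4.73 (SE 0.28, adjusted p = 1.34e-06). Its near-identical copy CXorf49 had almost the same values (39.1 and 39.0 in the RBM3 libraries), so the reads of this pair cannot be assigned with certainty. C12orf75 (ENSG00000235162, chromosome 12, 105235290 to 105396097) rose by a log2 fold change of 4.71, from 0.667 ± 0.238 to 19.4 ± 1.88. TGM2 (ENSG00000198959, chromosome 20, 38127387 to 38166578) had a log2 fold change of 4.24 (SE 0.40). C15orf48 (ENSG00000166920, chromosome 15, 45430529 to 45448761) had the same log2 fold change of 4.24 with a smaller error (SE 0.20). MGMT (ENSG00000170430, chromosome 10, 129467184 to 129768007) followed at 3.74. TMEM98, a transmembrane protein gene, rose from 3.05 ± 1.41 to 28.9 ± 0.60. The largest decrease by the same rule was that of LSP1, an actin-binding protein of leukocytes (ENSG00000130592, chromosome 11, 1852970 to 1892267), with a log2 fold change of -3.80 (SE 0.27, adjusted p = 4.32e-06) and means of 13.7 and 0.897. KRT14 (ENSG00000186847, chromosome 17, 41582279 to 41586921) came next at -3.57 (SE 0.11, adjusted p = 2.44e-08). NPDC1 fell from 31.6 ± 2.67 to 2.67 ± 0.71 and the secreted protease HTRA3 from 22.9 ± 1.75 to 3.71 ± 0.51. CDH5, the cadherin of endothelial junctions (ENSG00000179776, chromosome 16, 66366622 to 66404786), fell from 23.3 ± 13.7 to 2.12 ± 0.52, with 1 control library at 39.2 and the others at 16.4 and 14.4. CDH5 was the only 1 of 8 endothelial markers in the table. Among the 332 called genes with a mean abundance of at least 5, 11 were at least 8-fold higher and 4 at least 8-fold lower.

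Of the keratinocyte and epithelial lists fixed beforehand, none passed the camera test, and their listed members went in different directions. Genes beside the 2 chosen per list by rule are named after their values were seen. All 4 listed members of the basal keratinocyte list (of 20) fell: KRT14, KRT15 (1871 ± 286 to 484 ± 56.2), the desmosomal plakophilin PKP1 and TRIM29. By camera against the other listed genes this list had an adjusted p of 0.0883. All 4 listed members of the epithelial junction list (of 22) rose, among them the simple-epithelium keratin KRT18 (405 ± 11.9 to 994 ± 39.3) and the tight junction protein occludin, OCLN (4.99 ± 1.58 to 15.4 ± 2.42). The other two were KRT8, the partner of KRT18, and CLDN4 (camera adjusted p = 0.128). In the keratinocyte differentiation list, 8 of 34 members were listed. KRT13, the protease KLK7 (3.22 ± 1.38 to 12.8 ± 0.74) and, at low values, SPRR2D (0 to 0.863) rose. KRT4, TGM1, KLK5, CSTA and, also at low values, FLG (0.203 to 0.0167) fell. The log2 changes of the 8 listed members had a median of -1.33 and a mean of -0.267, and the camera adjusted p was 0.364. KRT13 was at 849 ± 117 in the control and 3257 ± 202 with RBM3. S100A9, the only listed member of the wound keratinocyte list, fell from 12.1 ± 3.33 to 4.11 ± 0.30. Of the mesenchymal list, FN1, COL6A1 and COL6A2 rose and CDH11 fell, all from means under 5 in both groups (camera adjusted p = 0.346).

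**Figure D2:**
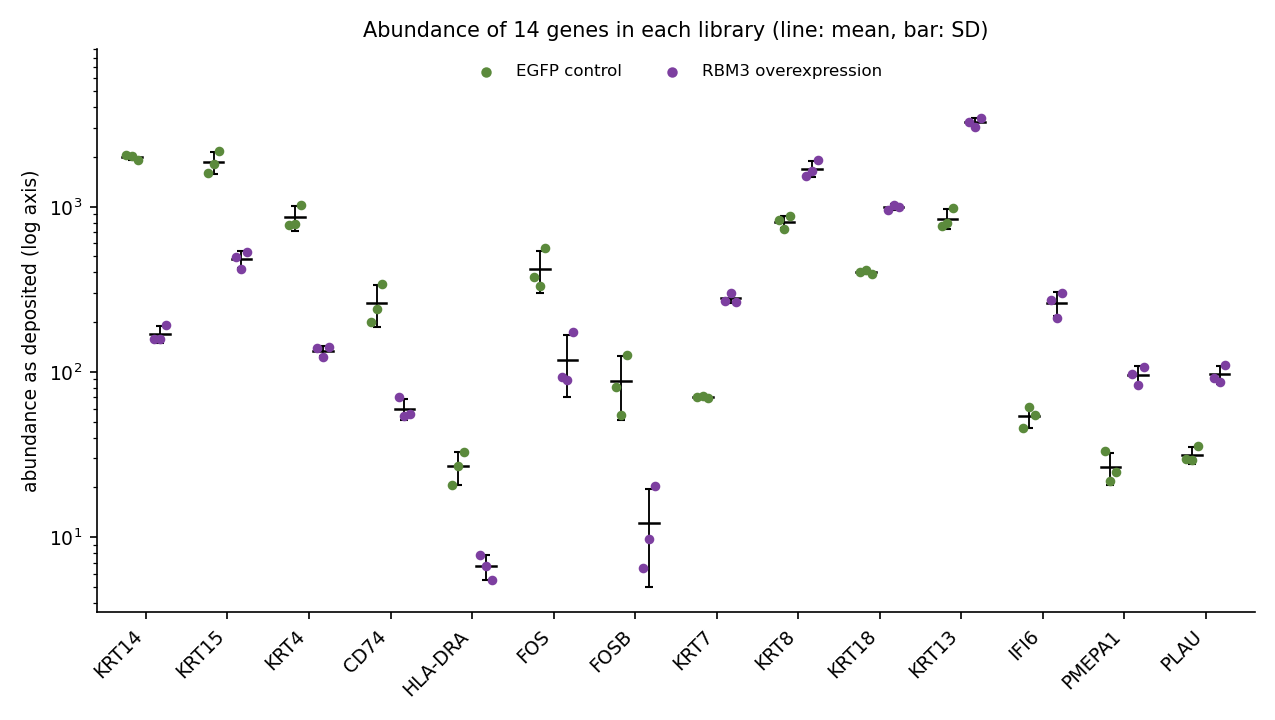
Deposited abundance (vertical axis, log scale, no stated unit) of 14 genes, chosen after their values were seen, in each of the 6 libraries, as points coloured by group, with the mean as a line and the SD as a bar. KRT14, KRT15, KRT4, CD74, HLA-DRA, FOS and FOSB lie lower with RBM3, and KRT7, KRT8, KRT18, KRT13, IFI6, PMEPA1 and PLAU lie higher, with no overlap between groups.

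Growth factor and matrix genes followed 2 directions. Of the list of EGF receptor ligands and MAPK response genes, 10 of 30 members were listed, and 7 rose and 3 fell. The ligands AREG (11.5 ± 0.81 to 24.4 ± 0.35) and HBEGF (5.79 ± 0.38 to 12.6 ± 2.53) rose, as did DUSP4, SPRY4, ETV4, ETV5 and FOSL1. The immediate early transcription factor genes FOS (423 ± 121 to 119 ± 47.7), FOSB (87.7 ± 36.7 to 12.2 ± 7.21) and EGR1 (140 ± 18.6 to 69.3 ± 14.2) fell. Replicate 3 of each group was the highest of its group for all of FOS, FOSB and EGR1, and also had the highest sum of values over the table in its group (19175 and 19525). By camera against the other listed genes the list had an adjusted p of 0.364. All 4 listed TGF-beta targets (of 20) rose, among them PMEPA1 (26.6 ± 5.83 to 95.8 ± 12.1), ITGB6 and BHLHE40 (camera adjusted p = 0.123). Of 6 listed matrix protease genes, 4 rose and 2 fell. The urokinase gene PLAU rose from 31.4 ± 3.62 to 96.7 ± 12.1, and its receptor PLAUR, ADAM19 and MMP9 were also higher. MMP28 fell from 55.2 ± 2.82 to 19.5 ± 1.12, and MMP13 was lower. The values of MMP9, at low means of 0.01 and 0.243, and of MMP13 overlapped between groups, and the list had a camera adjusted p of 0.510. Of 4 YAP/TEAD targets, ANKRD1 (at low values, 0.03 to 1.89), NT5E and DLC1 (3.82 ± 1.24 to 11.5 ± 3.72) rose and CCN2 fell (camera adjusted p = 0.346).

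Interferon-induced genes rose together. All 11 listed members of the type I interferon list (of 34) were higher with RBM3, led among abundant genes by IFI6 (53.7 ± 7.81 to 261 ± 44.3, log2 fold change 2.28, SE 0.16) and the RNA-sensing synthetase OAS2 (5.92 ± 1.69 to 17.6 ± 3.96). Their median log2 change was 1.48. Changes of about this size are common in the table, since 336 listed genes with a mean of at least 5 had a median absolute log2 ratio of 1.28. This median covers only the listed members and does not describe the whole programme. For these 11 genes, camera with a preset correlation of 0.01 gave an adjusted p of 0.0359. This was the only 1 of the 14 lists tested that passed, and it did not with an estimated correlation (adjusted p = 0.418). The list's adjusted p was also above 0.05 without control replicate 2 (0.0515) and with only genes at 1 or more in at least 3 libraries (0.0756). With a block by the submitters' second set of replicate numbers it was 0.0535. In that block control replicate 1 and RBM3 replicate 3 share their number with no other library, so they add nothing to the contrast. Of the NF-kB list, TNF, CSF2, PTGS2 and IRAK2 rose from means under 1 in the control, whereas TNFAIP3 was at 3.62 ± 1.57 and 6.68 ± 3.75 and was not called (adjusted p = 0.081). The list had a camera adjusted p of 0.123.

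Stress and metabolic lists held a few members each. All 5 listed members of the amino acid and unfolded protein response list (of 27) rose, including DDIT3, the transcription factor CHOP (17.04 ± 2.25 to 41.7 ± 1.71), and the endoplasmic reticulum protein gene MANF (45.3 ± 3.94 to 102 ± 5.14). The chaperone HSP90B1, EDEM1 and the cystine transporter SLC7A11 were the others (camera adjusted p = 0.123). All 4 listed NRF2 targets (of 24) rose: TXNRD1, SLC7A11 (3.57 ± 0.57 to 7.72 ± 0.52), AKR1C1 (27.9 ± 4.44 to 61.7 ± 2.60) and AKR1C3, with a camera adjusted p of 0.138. The AKR1C genes are close paralogs and uncertain. All 4 listed clock genes (of 19) rose, among them the nuclear receptor NR1D1 (7.02 ± 0.28 to 18.8 ± 3.20) and BHLHE40 (13.04 ± 0.55 to 29.3 ± 3.01), beside NPAS2 and NR1D2 (camera adjusted p = 0.128). In the hypoxia list BNIP3 (2.53 ± 0.46 to 11.7 ± 0.25) and P4HA1 (10.1 ± 1.05 to 25.6 ± 2.67) rose and CA9 was at 1.37 ± 0.94 and 2.15 ± 0.44, not called (camera adjusted p = 0.197). The p53 targets CDKN1A, the cell cycle inhibitor p21 (20.2 ± 1.56 to 42.7 ± 5.96), and TNFRSF10B (19.0 ± 3.12 to 44.2 ± 8.23) rose. So did FKBP4 (49.2 ± 5.45 to 102 ± 10.5) of the heat shock list and HMGCS1 (19.0 ± 5.30 to 38.2 ± 6.61) of cholesterol synthesis. The Wnt target TNFRSF19 (0.0133 to 0.107) and the apoptosis gene HRK (0.13 to 0.423) were called higher at values near the rounding. Without control replicate 1 or 2 or RBM3 replicate 1 the call for HRK was lost (adjusted p between 0.0532 and 0.065). It was also lost with a block by the submitters' second set of replicate numbers (0.0647). That block takes control replicate 1 and RBM3 replicate 3 out of the contrast. By limma treat against a fold of 1.5 neither TNFRSF19 nor HRK was called (adjusted p = 0.143 and 0.102), and HMGCS1 also lost its call (0.0514).

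**Figure D3:**
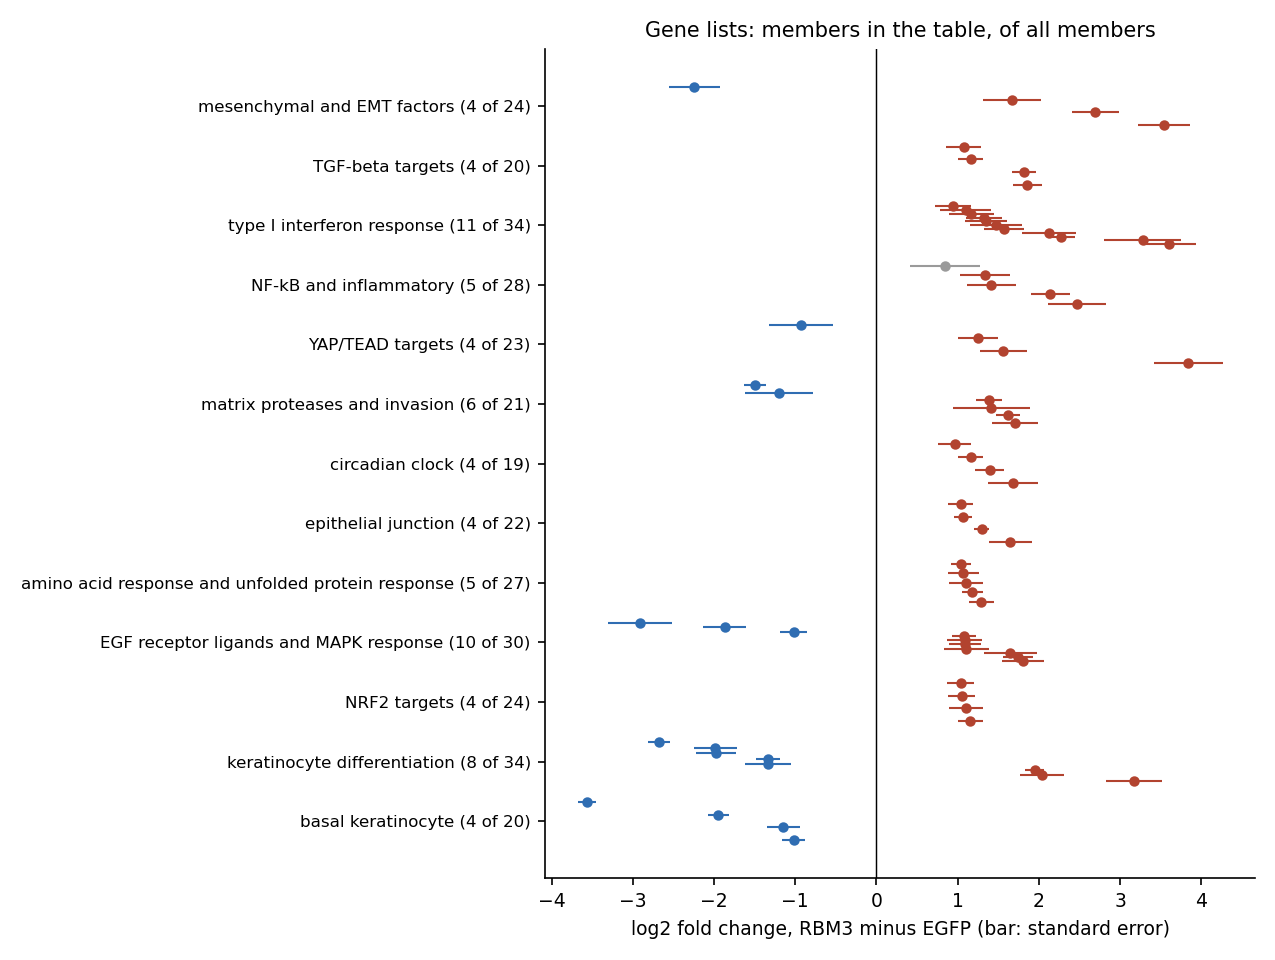
Log2 fold change of RBM3 minus EGFP (horizontal axis) of each listed member of the gene lists with at least 4 members in the table, 1 point per gene with its standard error as a bar, red for higher, blue for lower and grey for not called. All 11 interferon genes lie above 0 and all 4 basal keratinocyte genes below it.

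None of the fixed members of 8 lists was among the genes of the table: 29 splicing factors and hnRNPs, 20 genes of 3' end processing, 30 of S phase, 28 of mitosis, 16 of antigen presentation, 52 ribosomal proteins, 27 translation factors and 37 of oxidative phosphorylation. Since the listing criterion is not stated, absence from the table does not show that these genes were unchanged. None of the 18 melanocyte, 10 fibroblast, 10 leukocyte, 13 mitochondrial and 15 non-polyadenylated RNA markers was listed either. For each list, the counts adjusted over the list alone equalled those over all genes tested. With 1118 genes called both with and without adjustment, little else was possible, so this is no check of the lists. The p-values measure the spread between 3 libraries of each stable line, so a difference between the lines that arose during selection is part of the same contrast.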

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

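Tests with pseudocounts of 0.01 and 1 and with plain moderation were chosen after the data were seen; the others were planned. Counts of higher genes (593) stayed between 420 and 591 and of lower genes (525) between 359 and 547 over all alternatives, within 1.5 times of the main counts, with 556 to 583 higher and 476 to 513 lower when 1 library was left out. Called list members (79) stayed between 69 and 80. The number of lists called higher by camera (1, type I interferon) was 0 with values of at least 1 in at least 3 libraries, 0 with the second-label block, 0 to 1 when 1 library was left out (0 without EGFP control replicate 2), 0 with an estimated correlation and 12 with fry, which tests no contrast with other genes. The adjusted p of type I interferon reached 0.418 by camera, with the estimated correlation, and was 0.00168 by fry. Lists called lower by camera (0, and 1 at an unadjusted p under 0.05) came to 2 with fry and 1 with a pseudocount of 1 (basal keratinocyte). The causes were not tested. Apart from those, 8 values of named genes lost their call (6 of them HRK), and none changed sign. Deviations of libraries with the same title number correlated at -0.10, 0.09 and 0.08 across genes, which shows no pairing gene by gene. Such a correlation does not see an offset shared by all genes of a library. The scaling factors were highest for replicate 3 and lowest for replicate 2 in both groups, so pairing by title number is not excluded. A replicate block by the title numbers gave 590 higher and 526 lower genes, and one by the numbers of the second labels 513 and 487. In the block by second labels, control replicate 1 and RBM3 replicate 3 stand alone, so only libraries that share a second number are contrasted. Deviations of those libraries correlated at 0.08 and -0.09, which shows no pairing gene by gene. Count-based alternatives that were planned (DESeq2, voom, edgeR filters) and those about RBM3 were not run, since the table holds no counts and no RBM3. limma treat stood in for the edgeR test against a fold of 1.5 (451 higher, 359 lower). Depth, which limits low genes, is unknown.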

Other observations

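Gene families were counted after the values were seen, without a test of any family, and some of their members are also in the fixed lists. All 14 listed keratin genes, KRT87P among them, were called, 9 higher and 5 lower. KRT7, a keratin of simple epithelia, rose from 70.1 ± 1.04 to 279 ± 18.7 (SD, n = 3), and KRT80 from 227 ± 32.7 to 502 ± 70.7. The hair keratin genes KRT81 (33.9 ± 3.63 to 86.4 ± 19.4) and KRT85 (11.9 ± 3.51 to 30.2 ± 3.90) also rose, though they resemble each other in sequence and are uncertain. KRT3 and KRT9 fell with KRT14, KRT15 and KRT4. The claudins CLDN3, CLDN4 and CLDN23 were all higher. Of 5 kallikreins, KLK7 was higher and KLK4, KLK5, KLK9 and KLK13 were lower, with KLK13 at 20.5 ± 0.88 in the control and 7.66 ± 0.74 with RBM3. Of 23 zinc finger ZNF genes 15 were higher and 7 lower, and of 4 type IV collagens 1 was higher and 2 lower. Under the 3 scalings of the table no direction changed in these families or those below, but with the median of ratios 4 ZNF genes and COL4A3 lost their call, and with the upper quartile 1 ZNF gene did.

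Genes of MHC class II presentation fell, 6 of 6 listed. CD74, the invariant chain, went from 261 ± 73.5 to 59.9 ± 9.0 and HLA-DRA from 26.8 ± 5.99 to 6.63 ± 1.14, while none of the 16 genes of the class I presentation list was in the table. HLA-DRB1 and HLA-DRB5 are near-identical and uncertain. Lower values were also found for 7 transcription factor, phosphatase and RNA-binding protein genes of the immediate early response, picked after the values were seen: DUSP1 (41.4 ± 9.22 to 11.0 ± 2.07), ZFP36 (38.2 ± 6.67 to 15.97 ± 3.21), EGR2, NR4A1, FOS, FOSB and EGR1. Other early-response genes, PTGS2, HBEGF and FOSL1, were higher, so the direction is not that of the whole class. Of 241 annotation terms, 0 had an excess of one direction at an adjusted p under 0.05 by Fisher's exact test and 20 at an unadjusted one. Plasma membrane came nearest, with 171 genes higher and 96 lower (adjusted p = 0.0609).

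In the weighing that follows, the count over other splits, both tests of handling at harvest and the test of chromosomes within GC classes were chosen after the results were seen. The test of changes on chromosomes 14 and 16 was set before its result but prompted by the counts per chromosome.

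The direction of change was uneven over the chromosomes. The tests of this unevenness take genes as independent, although neighbouring called genes tended to share a direction, so their p-values may be too small. On chromosome 16, 7 of 56 called genes were higher (12.5%, exact binomial test against all called genes, adjusted p = 7.29e-09), and on chromosome 14, 7 of 44 (15.9%, adjusted p = 4.64e-06), whereas on chromosomes 4, 8, 12 and 20 the shares were 81.6%, 81.8%, 77.4% and 81.5%, with chromosomes 3 (49 of 66 higher), X (27 of 36) and 19 (38 of 100) also past the threshold (adjusted p = 0.00283, 0.0288 and 0.0082). GC content alone would give 47.97% on chromosome 16 and 52.6% on chromosome 14, and with directions shuffled within 10 classes of GC content the unevenness had a permutation p of 0.0005, the smallest that 2000 shuffles can give, which argues against GC content as its whole cause. A copy number of chromosomes 14 and 16 that differs between the stable lines may produce such a pattern and would crowd genes near the listing threshold, but the interval for a smaller change of their lower genes than of lower genes elsewhere includes 0.5 (AUC 0.462, 95% interval 0.399 to 0.527), so this cannot be told apart. An effect of RBM3 itself stays open and untested, since each group is a separately selected line, and no DNA was measured.

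Over all called genes, higher and lower genes had similar transcript lengths (AUC 0.488, 95% interval 0.455 to 0.521), which argues against a length bias that favours one direction. An effect of length on which genes were listed cannot be seen in this comparison. Higher genes had less GC (median 49.6%) than lower genes (54.8%), with an AUC of 0.383 (0.351 to 0.417) that lies between the bounds set for and against a GC bias, so such a bias may contribute and stays open. Neighbouring called genes 0.1 to 5 Mb apart shared a direction in 59.6% of 723 pairs (56.2% to 63.3%), against 50.2% after shuffling (permutation p = 1e-04, the smallest possible) and 56.5% after shuffling within chromosomes (p = 0.041). Copy number of smaller segments therefore remains open as well. By limma the real split gave 1118 called genes and the highest of the other splits 0 (at most 15 at an unadjusted p under 0.05). However, the genes appear to have been listed by the real split, and 10 splits (1 as large, the real one) are too few for a share under 0.05. The count over splits therefore says nothing about chance.

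The immediate early genes FOS, FOSB, EGR1 and DUSP1 fell while 7 of the 10 listed members of the MAPK response list rose, the 3 others being FOS, FOSB and EGR1. Such transcripts can respond quickly to handling, and the median SD of these 4 within groups was 0.379 (log2), against 0.193 for 149 listed genes of like abundance, at percentile 99.2 of random sets. Over all 7 genes counted above, with random sets matched on the abundance of each gene, which changes both the genes and the pool, the percentile was 88.6 as deposited, 81.6 after scaling to equal totals and 63.4 with the median of ratios. Replicate 3 was the highest of its group for 7 of the 7 genes in the control and 6 with RBM3 (7 and 5 after scaling to equal totals, 6 and 4 with the median of ratios), and it also had the highest sum over the table in each group. Handling at harvest may have contributed to the levels of these genes, but the tests depend on the genes, the pool and the scaling, so over the 7 genes it cannot be told apart from an effect of RBM3, which stays open and untested.

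Of the 105 listed genes whose groups overlapped, 56 were called, and they were less abundant than the separated genes (median 1.003 against 2.11, AUC 0.358, 95% interval 0.309 to 0.408). They did not clearly differ in the number of annotated transcripts (AUC 0.531, 0.472 to 0.585). The second labels number the RBM3 libraries 2 to 4 where the titles number them 1 to 3. The mention of C918 in the extraction protocol cannot be tested by melanocyte markers. The table holds mostly genes that differ between the groups, so the absence of these markers says nothing about their level. KRT8 was at 737 or more and KRT13 at 769.9 or more in each library, and KRT14 at 157.87 or more.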
